A study of Homo sapiens with 14 samples.

How the data were processed

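The study profiled single cells of the human embryonic stem cell line WIBR3 with a 10x droplet method that counts the 3' ends of transcripts by unique molecular identifier (UMI), with the v3.1 kit per the labels. The labels name 14 samples, each a single library without replicate: hTBLCs, sriZLCs at 60 h, hTBLCs in E8 medium at 6, 12, 36, 56 and 104 h, naive hESCs in E8 medium at 0, 33, 41 and 77 h, blastoids, and teratomas of primed hESCs and of hTBLCs. The submitters' processing notes name Cell Ranger and Seurat, without versions, and the genome builds hg38 and mm10.

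The tables the authors deposited hold raw UMI counts per gene and cell barcode, in whole numbers with totals that differ between cells. They had been filtered in different ways before submission, as the values show. Naive cells had at least 2001 genes and at most 5.0% mitochondrial UMIs, E8 cells at least 8007 UMIs, and blastoid cells at least 10108 UMIs; hTBLC and sriZLC barcodes went down to 500 and 501 UMIs. The gene lists differed too, 23366 genes for blastoids, 24361 for naive cells, 23821 for the E8 series, 33538 for hTBLCs and sriZLCs, and 40669 human and mouse genes for the teratoma. Barcode sequences of the naive series came from another pool than those of the other libraries. Naive and other libraries shared 12.87% to 26.95% of their barcode starts, against 97.13% or more among the others. These values argue against a single kit version for all libraries, as the labels give. Which kit the naive series had was not tested, and ratios of a naive to another library may cross kits. A gene missing from a table was treated as not measured there.

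Cell columns were matched to labels by their names, which covered 55212 columns and 12 libraries. Another 9887 columns carried names that match no label and were not used here; the naive 33 h library and the hTBLC teratoma were therefore not analysed here. Cells were kept at 1000 or more detected genes (500 in the teratoma) and 20% or less mitochondrial UMIs; teratoma barcodes also needed 90% or more human UMIs, and 6 mixed or mouse barcodes were left out. The filter removed 29.4% of hTBLC and 13.3% of sriZLC barcodes, 8 in the teratoma and 0 elsewhere.

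Cells kept, total UMIs (in units of 1000000) and median UMIs per cell were 2289, 88.5 and 32052 in naive 0 h, 3231, 127.5 and 34355 at 41 h, and 3329, 98.8 and 25441 at 77 h. They were 4167, 114.7 and 23298 in hTBLCs and 5118, 88.0 and 15386 in sriZLCs. The E8 series gave 6601, 127.0 and 18123 at 6 h, 4919, 114.1 and 21544 at 12 h, 4573, 106.3 and 21946 at 36 h, 3657, 109.1 and 27957 at 56 h, and 4350, 77.7 and 16947 at 104 h. Blastoids gave 4663, 119.3 and 22369, and the teratoma 5787, 68.5 and 10426. A single UMI was 0.00872 CPM in hTBLCs (the value of H3.Y there), so counting error is under 1% for POU5F1 and wide below 1 CPM.

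UMIs were summed per library and scaled to a library total of 1000000 (counts per 1000000, CPM). Levels carry exact Poisson intervals and ratios exact conditional binomial intervals, both at 95%. These cover counting alone, since 1 library per group allows no test between groups and no count of changed genes across the genome. A gene was called at 2-fold or more with an interval excluding 1. A ratio against 0 UMIs was given as a bound from a floor of 3 counts, with no ratio where both libraries had 3 counts or fewer. The comparisons were hTBLC over naive 0 h, sriZLC over hTBLC, each E8 time over 6 h, E8 6 h over hTBLC, naive 41 h and 77 h over 0 h, and the E8 series beside the naive series.

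Fixed gene lists were written before the data were examined: 10 of cell states (8-cell or zygotic activation, naive, primed and core pluripotency, oocyte and maternal, trophectoderm, hypoblast, amnion, mesendoderm, neuroectoderm), 7 of programmes (spliceosome, SR and hnRNP proteins, p53 targets, integrated stress response, cell cycle, DNA methylation, glycolysis) and 18 of teratoma cell types. A list was summarised by the median log2 ratio of its members with more than 3 UMIs in either library, an interval from 1000 Poisson resamples, and its percentile among 10000 random lists matched in 20 bins of mean expression. Single genes were named by a rule also fixed before the data were examined: up to 4 members per list with the largest ratio at 20 CPM and 30 UMIs or more in the higher library, the 10 highest and 10 lowest ratios at 50 CPM or more, and 15 fixed regulators. Mitochondrial, ribosomal protein and Y-linked genes and XIST were not named, nor were clone identifiers among the highest and lowest ratios. Gene positions are from GENCODE release 29 on GRCh38.

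Shares of cells with at least 3 genes of a list, or with a UMI of a gene, were computed after thinning each cell to 5000 UMIs and beside the unthinned share. Blastoid and teratoma cells were clustered with scanpy on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Doublets were called with Scrublet at an expected rate of 0.06 and removed from the teratoma (150 cells); in blastoids 41 were called and kept. A cluster took the name of the list with the most raised markers, at least 3 at 10 CPM and 2-fold over the other cells. It stayed unnamed on a tie, or where more of its 10 leading genes belonged to another list than to its own. A lead of a single marker over the next list also left it unnamed, unless its leading genes favoured its own list. So did a low depth with no marker of its own list among the leading genes. Clusters of core, naive or primed markers were joined as pluripotent. Shares carry exact binomial intervals.

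Alternatives tried were every barcode, a stricter cell filter (2000 genes and 10% mitochondrial UMIs), TMM scaling, CPM without mitochondrial and ribosomal protein genes, mean per-cell CPM, thinned cells, members of at least 10 CPM, Leiden resolutions 0.5 and 2.0, 4000 variable genes, doublets treated the other way, naming cell by cell, and thinning to 2000 or 10000 UMIs. The ratio procedure was tested on simulated data with 8306 genes of at least 10 CPM in hTBLCs and counting error only. Fainter genes were not covered by it. Of 50 genes each raised or lowered 3-, 4- or 8-fold all 50 were called. Of 50 raised or lowered 1.5-fold 0 were called, and of 8106 unchanged genes 0 were called. At these levels the 2-fold limit made both zeros likely in advance. The simulation says nothing about variation between libraries. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (TMM factors only).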

Results

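The libraries profiled cells of WIBR3, a human embryonic stem cell line, in the states their labels name: naive hESCs, hTBLCs, sriZLCs at 60 h, blastoids, and a teratoma grown from primed hESCs. The design asks which pluripotency and early-embryo genes each state expressed, how hTBLCs and naive hESCs changed in E8 medium, and which cell types the blastoids and the teratoma held. Levels are UMI counts scaled to a library total of 1000000 (CPM). Each group was 1 library, so the ranges in square brackets are 95% intervals of counting error only and no difference has a replicate check. A gene was called higher or lower at 2-fold or more with the interval clear of 1. The percentile of a list among 10000 random lists of matched expression describes these libraries and is not a test.

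The hTBLC library expressed primed pluripotency genes at high levels, and naive and 8-cell genes were nearly absent from it. THY1, a surface glycoprotein of primed stem cells, was 1609-fold higher [899.2, 3224] than in naive hESCs at 0 h, where it stood at 0.124 CPM. The secreted Wnt modulator SFRP2 stood at 502.2 against 0.17 CPM, the MAP kinase phosphatase DUSP6, a readout of FGF signalling, at 176.1 against 0.113 CPM, and the zinc-finger factor ZIC2 at 50.3 against 0.588 CPM. In the other direction DNMT3L, a cofactor of de novo DNA methylation that marks naive cells, was 8523-fold lower [3652, 26250], at 0.0436 against 371.6 CPM. DPPA5, an RNA-binding protein of naive cells, had no UMI in hTBLCs against 1723 CPM. The maternal-effect gene NLRP7 gave 0.00872 against 286.4 CPM, from a single hTBLC UMI. DPPA3 (chromosome 12, 7711454 to 7717559), which protects the oocyte genome from methylation changes, was 15340-fold lower [2752, 605900], again from 1 UMI.

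As groups, all 20 primed genes were higher in hTBLCs, with a median log2 ratio of 5.56 (random lists 0.84). Of the 20 naive genes, 18 were lower and 0 higher, with a median of -7.86 (random lists 0.81). The 8-cell list, built from genes switched on at zygotic genome activation, had 28 measured members, of which 25 were lower and 0 higher; its median was -4.82 [-4.93, -4.50] against 1.39 for random lists, and 17 members had no UMI in 1 of the libraries. Its summed level was 8.55 CPM in hTBLCs and 929 CPM in naive hESCs. Most of the naive signal came from KHDC1L (chromosome 6, 73223544 to 73225770), at 804.7 against 0.288 CPM. The 8-cell transcription factors were faint even in naive hESCs: TPRX1 stood at 2.48 CPM, LEUTX at 1.39, DUXA at 0.746 and ZSCAN4 at 0.192 CPM, and none of the 4 had a UMI in hTBLCs. KLF17, a naive transcription factor, was at 0.124 CPM in naive hESCs and had no UMI in hTBLCs. Members of near-identical families (PRAMEF, TRIM43, TRIM49, MBD3L, RFPL4) can share reads, so their single values are uncertain.

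The core pluripotency genes split. POU5F1 (chromosome 6, 31164337 to 31180731), the central factor of every pluripotent state, was at 1036 CPM in hTBLCs and 1121 CPM in naive hESCs, inside 2-fold in CPM. SOX2 was 16.1-fold higher in hTBLCs and the RNA-binding protein LIN28A 17.7-fold higher, whereas the homeobox factor NANOG was 3.77-fold lower. ZFP42, a zinc-finger gene of naive and mouse stem cells, had no UMI in hTBLCs against 80.4 CPM, at least 3072-fold lower. Germ-layer genes were present in hTBLCs at low levels: the endoderm factor FOXA2 reached 42.8 against 0.339 CPM and the mesendoderm list had a median of 3.82, with a summed level of 46.0 against 31.5 CPM. SOX17, an endoderm factor, was 2.06-fold higher at 3.11 CPM, GATA4 4.12-fold lower at 0.741 CPM, and GATA3 was within 2-fold.

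Glycolysis genes were lower in hTBLCs, and single stress and splicing genes differed widely. LDHA (chromosome 11, 18394388 to 18408425), which turns pyruvate into lactate, was 8.02-fold lower in hTBLCs [7.91, 8.14], and the glycolysis list had a median of -1.19, with 8 of 13 genes lower and 0 higher. The integrated stress response list had a median of 1.42 (random lists 0.40), led by the apoptosis-linked factor DDIT3, 7.95-fold higher, and the serine synthesis enzyme PHGDH at 535.4 against 116.3 CPM. CDKN1A, the cell-cycle inhibitor downstream of p53, was 17.4-fold lower. SF3B1, a core U2 snRNP protein (chromosome 2, 197389784 to 197435091), was 13.7-fold higher in hTBLCs, at 316.1 against 23.1 CPM.

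Scaling and library preparation limit the small differences of this comparison. The naive libraries came from another barcode pool than all others, so preparation and cell state are confounded here. TMM scaling moved every ratio by -1.03. The median log2 ratio of hTBLCs to naive cells was 0.95 over the 8855 genes at 10 CPM or more in either library and -0.24 over the 8906 genes passing that limit with TMM, a partly different set. With TMM the core pluripotency median went from 0.94 to -0.089, the spliceosome from 0.45 to -0.58, SR and hnRNP proteins from 0.56 to -0.47, the cell cycle from 0.54 to -0.49 and DNA methylation from 0.70 to -0.33, so no direction is given for these lists. The p53 target list (0.08, against -0.95 with TMM) lay at percentile 0.74 of the random lists. Of single genes, POU5F1 went from -0.11 to -1.14, past 2-fold, and SOX17 from 1.04 to 0.012, so neither call holds under both scalings. With TMM the stress response median dropped to 0.40, the hypoblast median from 1.04 to 0.012 and the neuroectoderm median from 1.57 to 0.55. The trophectoderm list had a median of -0.80 (random lists 1.15), with 11 of 22 members lower and 5 higher, and the amnion list 0.21 (-0.82 with TMM). The oocyte and maternal list was at -0.79 (-1.82 with TMM). It turned to 0.14 with a stricter cell filter, to 0.61 after thinning and to 2.91 among members of at least 10 CPM.

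**Figure D1:**
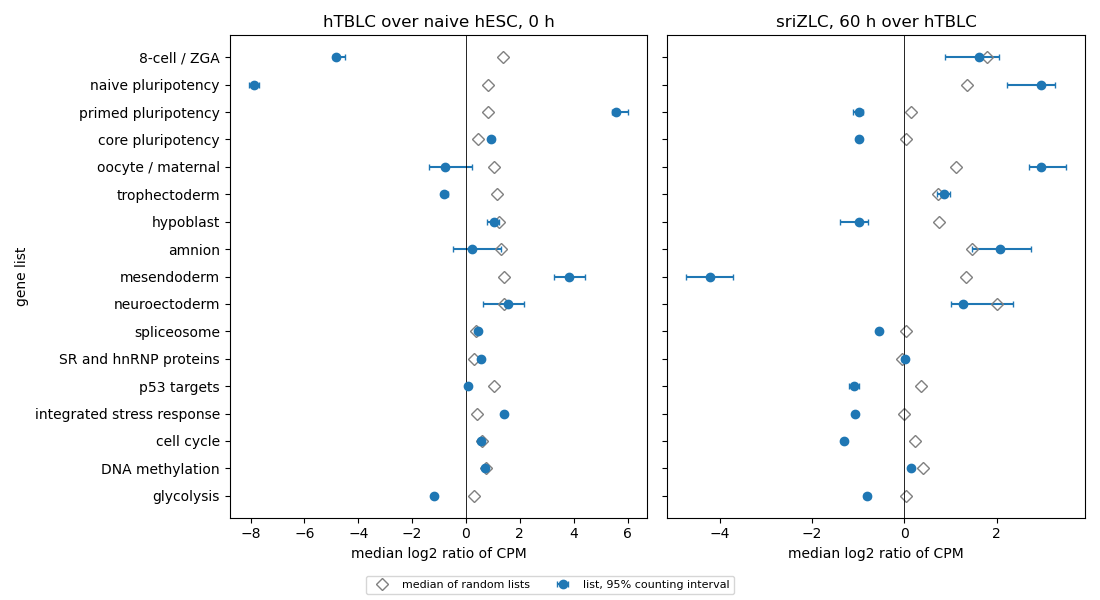
Median log2 ratio of CPM for each of 17 gene lists, in hTBLCs over naive hESCs at 0 h (left) and in sriZLCs at 60 h over hTBLCs (right); filled points carry 95% counting intervals and open diamonds are the medians of matched random lists. The naive (-7.86) and 8-cell (-4.82) lists lie far left and the primed list (5.56) far right in the left panel, and mesendoderm (-4.21) lies furthest left in the right panel; on the left, core pluripotency, amnion, spliceosome, SR and hnRNP, p53, cell cycle and DNA methylation change sign with TMM scaling.

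The sriZLC library at 60 h differed from hTBLCs by oocyte-type transcripts that rose and by several primed, mesendoderm, hypoblast and cell-cycle transcripts that fell. GDF9 (chromosome 5, 132861181 to 132866884), an oocyte growth factor, was at 30.4 CPM against 0.0174 CPM, 1744-fold higher [482.3, 14410], with 2 UMIs in hTBLCs. OOEP (chromosome 6, 73368555 to 73395133), part of the subcortical maternal complex of oocytes, rose to 81.1 from 0.0698 CPM. The 8-cell factors came up from no UMI at all, but stayed faint: TPRX1 reached 1.48 CPM, at least 56.5-fold higher, ZSCAN4 (chromosome 19, 57668935 to 57679152) 0.909 CPM, and DUXA 0.0796 CPM. KLF17 was at 0.0682 CPM. DNMT3L was 6.52-fold higher [2.45, 21.8] at only 0.284 CPM, and DPPA3 stayed at or near the counting floor in both libraries.

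The maternal list had a median of 2.97 [2.70, 3.50] against 1.12 for random lists, with 11 of 15 measured genes higher and 1 lower. Its summed level was 221.2 against 100.8 CPM. The sum is not of oocyte transcripts alone, since the list shares the epiblast gene OTX2 with the primed list. The naive list had the same median of 2.97, with 13 of 18 higher, but from low levels, 69.1 against 12.8 CPM in sum. DPPA2, a germline and naive gene, rose 12.3-fold to 26.5 CPM. The 8-cell list was at 1.60 with 8 of 16 genes higher and 3 lower, which was close to the random lists at 1.79, and at 16.6 CPM in sum it stayed far under the 929 CPM of naive hESCs. Its median was under 2-fold with the stricter cell filter (0.67) and among members of at least 10 CPM (0.98).

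Several primed, core and endoderm genes were lower in sriZLCs. VIM, the mesenchymal and primed filament gene, fell 15.2-fold from 957.6 CPM, and ZIC2 and DUSP6 fell 4.28-fold and 3.16-fold. The primed median was -0.99 (random lists 0.14), with 10 of 20 members lower and 4 higher. OTX2, an epiblast homeobox gene that is on the maternal list too, was among those higher, at 74.8 against 10.7 CPM. POU5F1 was level, 1035 against 1036 CPM with a ratio of 0.998 [0.990, 1.007], while SOX2 fell 4.34-fold, NANOG 3.69-fold and the chromatin factor DPPA4 8.41-fold; the core list was at -0.98. FOXA2 fell from 42.8 to 1.09 CPM and the lipoprotein gene APOA2 from 91.5 to 0.239 CPM. The mesendoderm median of -4.21 was below all random lists (6 of 9 lower), and the hypoblast median was -0.97. SOX17 was 4.15-fold lower, but GATA4 14.3-fold higher at 10.6 CPM. KRT18, an epithelial keratin, fell 8.30-fold; the trophectoderm median of 0.85 turned to -2.13 among members of at least 10 CPM. The amnion list was at 2.07 (random lists 1.46) and the neuroectoderm list at 1.28 (random lists 2.01), the last under 2-fold after thinning (0.91).

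Splicing genes went both ways. The kinase CLK1, which phosphorylates SR proteins, rose 9.30-fold to 135.8 CPM, and the splicing regulator TRA2A rose from 39.0 to 292.3 CPM. PRPF8, the catalytic-core scaffold of the spliceosome, was 3.42-fold higher and the U5 GTPase EFTUD2 3.74-fold higher, while SNRPA1 fell 2.95-fold, SRSF9 5.99-fold and HNRNPU 5.20-fold. The spliceosome median was -0.56, with 4 of 25 higher and 6 lower, and the SR and hnRNP median 0.00, with 3 of 22 higher and 5 lower. The cell-cycle list fell: 15 of 20 genes were lower and 0 higher, with a median of -1.31 (random lists 0.22). TYMS, which makes thymidylate for replication, fell 18.4-fold and the mitotic antigen MKI67 7.56-fold. p53 targets were at -1.10, led by the cytokine GDF15 (57.4 to 1.10 CPM), stress response genes at -1.06, and glycolysis at -0.81. DNA methylation genes split, with a list median of 0.14: the demethylating dioxygenases TET2 and TET3 rose 10.6-fold and 13.7-fold, and the maintenance methylase DNMT1 fell 4.71-fold. Against random lists matched on gene length too, the core (percentile 24.4), stress response (12.5), glycolysis (17.2) and spliceosome (33.4) lists were not unusual, the primed (7.71) and p53 (5.18) lists were less extreme than without it, and mesendoderm and hypoblast stayed at 0 and 0.98. The median of all genes was 0.15 in CPM over 10649 genes and -0.058 with TMM over the 9740 genes that then passed the expression limit.

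Single cells showed whether these lists came from few or many cells. After each cell was thinned to 5000 UMIs, 97.2% of naive 0 h cells held at least 3 naive genes, and 0% of hTBLCs did (100% and 0.504% unthinned, at median depths of 32052 and 23298 UMIs). For the primed list the order was reversed, 99.4% of hTBLCs and 0.832% of naive cells. At least 3 genes of the 8-cell list were seen in 2.93% of thinned naive 0 h cells, 24.5% unthinned, with hTBLCs as the background at 0% and 0.0960%. In sriZLCs the share was 0.0207% thinned and 0.0977% unthinned at a median of 15386 UMIs, level with that background, whereas at least 3 maternal genes were seen in 4.26% of thinned sriZLCs against 0.0257% of hTBLCs (39.1% and 3.24% unthinned). TPRX1 alone was found in 0.952% of thinned sriZLCs and 2.36% unthinned, with 0% of hTBLCs either way. Most sriZLCs held at least 3 genes of the primed list, 92.4% after thinning and 96.9% unthinned. This does not show a primed state, as the list is not specific to it. Its sum was 1675 CPM in sriZLCs and 3145 CPM in hTBLCs, but 7687 CPM in the teratoma.

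In E8 medium, hTBLCs at 6 h (the library labelled r6h, the last of the series being r104h) already expressed primitive-streak and endoderm genes above the hTBLC library. LEFTY1, a NODAL antagonist of the streak, was at 132.0 against 1.67 CPM, 78.8-fold higher [68.4, 91.4]. The streak homeobox gene MIXL1 (chromosome 1, 226223618 to 226227054) was 18.3-fold higher and LHX1 18.4-fold, and CER1, a secreted antagonist from anterior endoderm, stood at 22.5 against 3.55 CPM. All 9 measured mesendoderm genes were higher, with a list median of 2.76 [2.67, 2.91], and 13 of 18 hypoblast genes with a median of 1.47. Stress genes were lower at 6 h: DDIT4 by 20.2-fold, DDIT3 by 13.8-fold and the stress-induced NUPR1 by 40.7-fold, with 11 of 12 stress response genes lower and a median of -1.74. The core list was at -0.48 and the primed list at 0.02.

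Over the time course the streak genes faded from their 6 h level, while glycolysis and stress genes rose from theirs. Beside the hTBLC library the summed stress response list did not end higher. It was at 2244 CPM in hTBLCs, 741.0 CPM at 6 h and 2089 CPM at r104h. Glycolysis genes summed to 6342, 6604 and 24040 CPM in that order. Mesendoderm genes summed to 46.0, 468.7 and 86.8 CPM, with 10 genes listed for hTBLCs and 9 for the E8 series. MIXL1 fell from 112.6 CPM at 6 h to 21.3 CPM at 56 h and 2.07 CPM at r104h, 54.4-fold below 6 h. EOMES, another streak factor, was at 61.7, 23.7 and 5.98 CPM at these times, and LHX1 fell 3.97-fold by r104h. Among endoderm genes, SOX17 fell 5.14-fold from 14.03 CPM, GATA4 9.70-fold and APOA2 7.15-fold. LDHA rose from 211.8 to 961.7 and then 2089 CPM, the glucose transporter SLC2A1 from 116.2 to 622.6 and 1120 CPM, and the mTOR inhibitor DDIT4 (chromosome 10, 72273920 to 72276036) from 13.7 to 501.8 and 921.6 CPM.

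At 12 h no list moved by 2-fold, and the largest median was -0.26. At 36 h mesendoderm was the list that fell, to -1.09 [-1.33, -0.85], with 5 of 9 genes lower; averaging per-cell CPM gave -0.93 and thinning -0.84, under 2-fold. The neuroectoderm list was at 1.29 from only 2.24 CPM in sum, and at 0.21 with the stricter filter. At 56 h glycolysis reached 1.06 with 7 of 13 genes higher, and the stress response 0.92, with mesendoderm at -0.80. At r104h all 13 glycolysis genes were higher with a median of 1.80 [1.73, 1.84], and the stress response was at 1.85. Mesendoderm was then at -1.99, with 6 of 9 genes lower, and the cell cycle at -1.14, with 12 of 20 lower and 0 higher; RRM2, which supplies deoxynucleotides, fell 4.13-fold. Hypoblast genes ended at -1.05, which was -0.97 with TMM scaling and -0.95 as a mean per cell. The primed median was 0.52, within 2-fold, with 8 of 20 genes higher, and UTF1, a chromatin factor of the core list, rose from 2.69 to 87.4 CPM. POU5F1, SOX2 and NANOG stayed within 2-fold of 6 h, the core median being -0.47. Splicing lists stayed within 2-fold, at -0.48 for the spliceosome and -0.54 for SR and hnRNP proteins, though SRSF7, an SR splicing factor, was 3.73-fold lower. DNA methylation genes were at -0.68 and p53 targets at 0.30.

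The share of E8 cells with at least 3 mesendoderm genes followed the summed level, 12.4% at 6 h and 1.91% at r104h after thinning (31.3% and 4.44% unthinned, at medians of 18123 and 16947 UMIs). The hTBLC library gave 0.437% thinned and 5.88% unthinned, and naive 0 h cells 0% and 0.306%. Other lists stood low in the E8 series. The 8-cell list, with 11 of its 34 genes in the E8 tables, summed to 5.44 CPM at 6 h, 13.5 CPM at 56 h and 12.4 CPM at r104h, the neuroectoderm list to 1.24 CPM at 6 h and 6.17 CPM at r104h, and the amnion list to 22.9 CPM at 6 h. The naive list was at 14.04 and 39.0 CPM, and the maternal list at 80.3 and 55.99 CPM. ZSCAN4, TPRX1, LEUTX, DUXA and KLF17 had no entry in the E8 tables. Median mitochondrial UMIs per cell were 10.6% at 6 h and 2.67% at r104h. The median of all genes at r104h was -0.17 in CPM and -0.075 with TMM scaling.

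**Figure D2:**
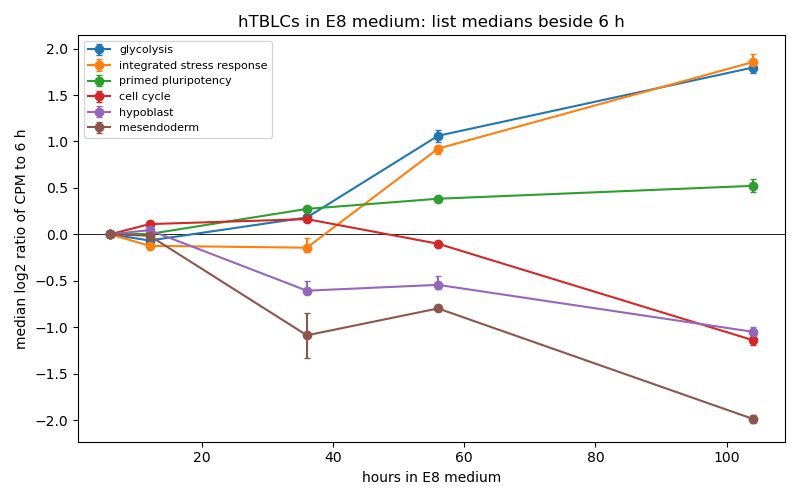
Median log2 ratio of CPM to the 6 h library for 6 gene lists against hours in E8 medium, with 95% counting intervals and 1 library per time. Glycolysis and the stress response climb to 1.80 and 1.85 by r104h, while mesendoderm drops to -1.99.

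Naive hESCs in E8 medium lost naive and 8-cell genes and gained primed genes between 0 and 77 h. DNMT3L went from 371.6 CPM to 82.1 at 41 h and 0.294 at 77 h, 1266-fold below the start [881.3, 1891]. DPPA3 was at 133.8, 80.8 and 5.18 CPM. KHDC1L kept its level at 41 h, 1189 against 804.7 CPM, and was then lost, 512.9-fold below the start at 77 h. THY1 rose early, 312.4-fold by 41 h to 38.8 CPM and to 188.3 CPM at 77 h, whereas SFRP2 (105.8 CPM), SOX11 (47.2 CPM) and ZIC2 (12.4 CPM) were gained mainly by 77 h, and DUSP6 reached 16.7 CPM. The de novo methylase DNMT3B rose 7.49-fold to 279.5 CPM.

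At 41 h the 8-cell list had a median of -1.53 [-1.78, -1.26] with 17 of 31 genes lower and 0 higher, although KHDC1L kept its summed level at 1256 against 929 CPM; among members of at least 10 CPM the median was -0.64. Among faint members TPRX1 was 3.71-fold and LEUTX 6.11-fold lower. Naive genes were at -0.75 and primed genes at 0.79. Of 21 trophectoderm genes 8 were higher at this time and 1 lower, with a median of 0.51 and a sum of 4686 against 2391 CPM. They included the keratin KRT18, 2.07-fold higher, and the transcription factor GATA3, 2.35-fold. CAV1, a caveolar protein, was among the largest gains, at 291.4 against 4.92 CPM. At 77 h KRT18 was 3.09-fold and GATA3 21.4-fold below the start, and the trophectoderm list was at -1.69 with 13 of 22 lower.

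By 77 h the naive list had a median of -4.29 [-4.40, -4.18], with 18 of 20 lower, the 8-cell list -3.62 with 25 of 28 lower, and the primed list 5.71 [5.50, 5.95] with 20 of 20 higher. Core pluripotency genes reached 1.15 with 6 of 12 higher, which TMM scaling brought to 0.66: SOX2 rose 8.15-fold and LIN28A 16.4-fold, while POU5F1 (1927 CPM) and NANOG (94.7 CPM) stayed within 2-fold. Glycolysis did not share the rise seen in the E8 series, with a median of -0.64 and LDHA 3.61-fold lower. Mesendoderm genes summed to 31.5 CPM at 0 h, 86.4 CPM at 41 h and 6.46 CPM at 77 h. HAND1, of early mesoderm and also trophoblast, made up most of this, at 25.6, 72.1 and 0.0911 CPM. Hypoblast (-1.55) and amnion (-1.10) medians rested on faint genes and changed sign under an alternative each, so no direction is given. The other programmes stayed within 2-fold: spliceosome -0.32, SR and hnRNP 0.04, cell cycle 0.29, stress response -0.30 and DNA methylation 0.13. Median log2 ratios of all genes were 0.20 in CPM and -0.32 with TMM.

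Per cell, 71.4% at 41 h and 3.24% at 77 h still held at least 3 naive genes after thinning (99.0% and 41.6% unthinned), and cells with at least 3 primed genes went from 0.832% to 5.85% and 96.3% (24.3%, 65.9% and 99.9% unthinned). The naive median depths were 32052, 34355 and 25441 UMIs. At least 3 primed genes were thus detected in nearly every cell by 77 h, though free RNA in the droplets was not estimated.

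**Figure D3:**
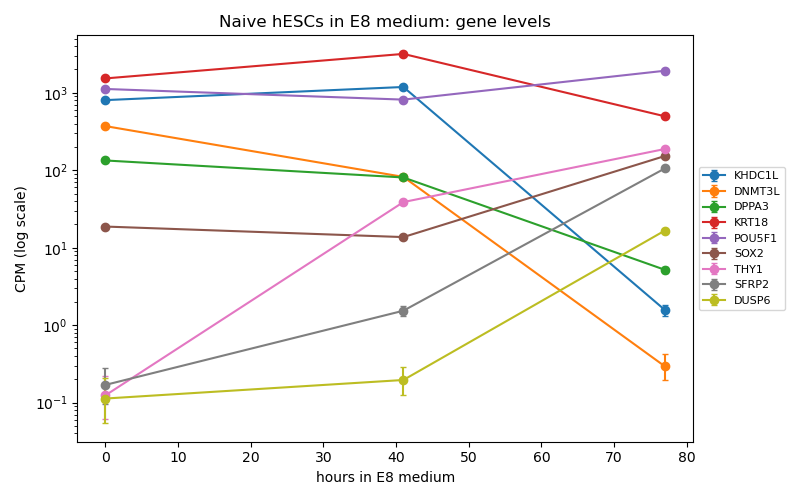
CPM of 9 genes, on a log axis, in the naive hESC libraries against hours in E8 medium, with 95% counting intervals and 1 library per time. KHDC1L drops only after 41 h, from 1189 to 1.57 CPM, and THY1 climbs from 0.124 to 188.3 CPM.

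Set side by side, the hTBLC and naive routes through E8 medium passed through different genes. At the earlier pair, hTBLCs at 36 h and naive cells at 41 h, all 17 measured naive genes were lower in the hTBLC series (median -8.16), primed genes were higher (5.36, 18 of 20), and mesendoderm (4.18) and hypoblast (3.35) genes were higher. At the later pair, r104h and 77 h, the primed difference was down to 1.52 and the naive difference to -2.06. DPPA5 was still at 87.1 CPM in naive cells at 77 h with no UMI in hTBLCs at r104h, and TDGF1, a NODAL co-receptor, was 16.5-fold lower in the hTBLC series. LHX1 was 152.9-fold higher there and APOA2 61.5-fold, with hypoblast and mesendoderm medians of 4.48 and 3.58. Glycolysis was at 1.69, SLC2A1 being 5.79-fold higher. The hours of each pair differ, and the 41 h library took the place of 33 h, which was not analysed here. All-gene medians were 0.74 and 0.42 in CPM, and -0.31 and -0.0022 with TMM.

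The blastoid library held pluripotent-like and endoderm-like cells, and no cluster was named trophectoderm by the rule. Of 4663 cells, 1637 (35.1% [33.7, 36.5]) fell in 4 pluripotent-like clusters; 3 of them raised POU5F1 and SOX2 over the other cells, and the last raised primed genes such as ZIC2 and PTPRZ1. Another 1320 cells (28.3% [27.0, 29.6]) were hypoblast-like. The most distinct of these, 394 cells, raised 13 hypoblast markers, among them GATA4, PDGFRA and APOA1, and was led by apolipoprotein APOA1 at 1245 CPM and the lipid transfer gene MTTP. The remaining hypoblast-like cells had 4 markers per cluster, with SOX17 and GATA6 in both. A cluster of 225 cells (4.83%) raised the mesendoderm genes EOMES, MESP1, MESP2, LHX1 and HAND1; MESP1, an early mesoderm factor, was 37.2-fold above the other cells. This class had 0 cells with coarser clusters and 7.91% when cells were named singly.

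No cluster was named trophectoderm, amnion, neuroectoderm, 8-cell or maternal, 0 of 4663 cells each. The blastoid table lists only 10 of 34 8-cell, 10 of 18 maternal and 19 of 22 trophectoderm genes, so these zeros say little about 8-cell and maternal states. In an unnamed cluster of 87 cells the trophectoderm-list factors NR2F2, TFAP2A and TFAP2C were raised beside as many primed genes. In another of 28 cells the amnion-list genes GABRP, IGFBP3, BMP4 and HEY1 stood beside HOXB1 and COL3A1. That cluster raised 3 hypoblast genes too, a single gene fewer, and no amnion gene led it, so it took no name. Unnamed cells were 1481 in all (31.8%), including 419 led by mitotic genes such as NEK2 and CENPE. Those 419 raised the hypoblast markers SOX17, FOXA2 and BMP2, a single marker more than of the next list. The hypoblast-like share above leaves them out. The shares depend on how cells were grouped. Hypoblast-like cells were 48.7% with coarser clusters, and naming each cell by its own markers, which leaves no cell unnamed, gave 8.71% trophectoderm and 8.79% amnion. The zeros thus reflect the naming rule and do not show that such cells were absent. Over the whole library the trophectoderm list summed to 5112 CPM, from 19 of its genes, the highest of 12 libraries, next to 4686 CPM in naive 41 h, 2577 to 3298 CPM in the E8 libraries, 2391 CPM in naive 0 h and 2113 CPM in hTBLCs, so these genes were expressed although no cluster took the name, as they were in the cultures.

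The primed hESC teratoma was mostly neural and mesenchymal. Mesenchyme-like cells, with LUM and PDGFRA raised in every such cluster, were 1247 of 5637 (22.1% [21.0, 23.2]). Neural progenitors, with SOX2 raised, were 1147 (20.4% [19.3, 21.4]), and neurons 834 (14.8%). The neurons separated by region and transmitter: NEUROD6, of cortical excitatory neurons, was at 1071 CPM in a cluster of 87 cells, DLX5, of forebrain inhibitory neurons, at 638.8 CPM in 102 cells, and SLC17A6, the vesicular glutamate transporter, at 229.7 CPM in 377 cells. Small clusters carried lineage genes. Skeletal muscle (33 cells) raised MYOG and MYOD1, cartilage (27 cells) MATN1 and ACAN, pigmented retina (54 cells) DCT, and a Schwann-like cluster (49 cells) CDH19 beside the pigment gene MLANA. Blood-like cells numbered 37 (0.656%).

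A further 2209 cells (39.2%) had no name by the rule, often because markers of more than 1 list were raised. The largest such cluster, 677 cells, raised SOX2 and PAX6 and was led by LIN28A and the eye-field gene SIX3. A cluster of 219 cells raised 8 neuron markers and was led by SLC6A5, but LHX1 and PAX8 of the kidney list were among its leading genes. Clusters of 107 and 409 cells raised 8 mesenchyme markers each. The neuron and mesenchyme shares above leave these cells out. A cluster of 257 cells joined 7 ciliated genes such as FOXJ1 to TTR at 115600 CPM, a pairing found in choroid plexus. Another, of 39 cells, raised AFP, APOB and FGB, of yolk sac and liver, beside as many gut genes. No cluster was named smooth muscle, endothelium, gut, yolk sac or liver, squamous, ciliated, kidney, trophoblast or undifferentiated, 0 of 5637 cells each, and proliferation was never used to name a cluster. These zeros reflect the naming rule: finer clusters gave 32 smooth muscle cells (0.568%), and naming cells singly gave 4.74% smooth muscle, 5.27% ciliated and 2.45% endothelium. Small classes moved as well. Skeletal muscle was 8.87% with coarser clusters and 0% with 4000 variable genes, pigmented retina 0% in both, Schwann-like cells 1.93% and 1.92%, and cartilage 1.22% with finer clusters, whereas blood-like cells numbered 37 under each of these settings. Mesenchyme was 35.3% with 4000 variable genes, and neurons were 6.60% with coarser clusters and 9.58% with 4000 variable genes. The hTBLC teratoma was not analysed here, so the 2 teratomas were not compared.

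**Figure D4:**
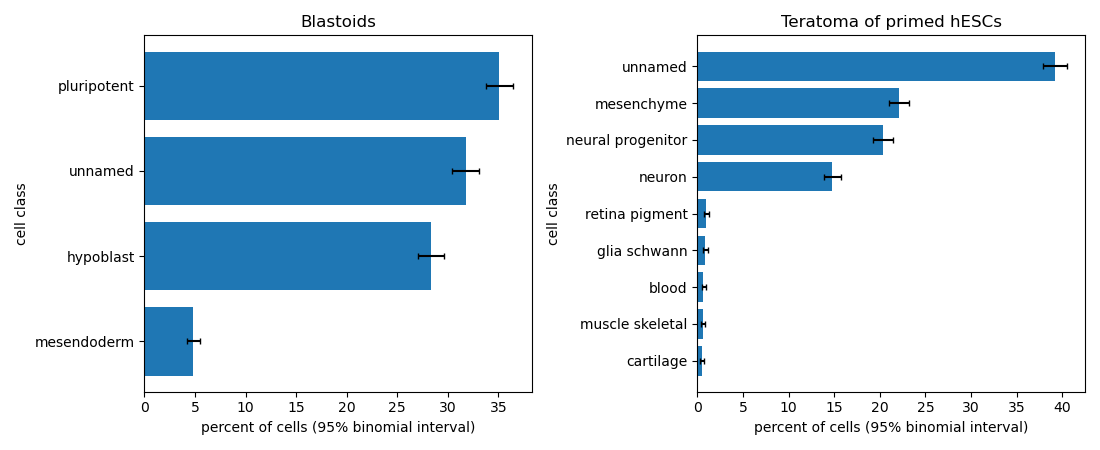
Percent of cells in each named class in the blastoid library (left, 4663 cells) and the primed hESC teratoma (right, 5637 cells), with 95% binomial intervals of cell sampling. Pluripotent-like cells were 35.1% of blastoid cells, and mesenchyme 22.1% and neural progenitors 20.4% of teratoma cells, with unnamed cells 31.8% and 39.2%.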

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

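The tests of the barcode pool, of the ribosomal protein share, of the stricter cell filter, of gene length and of free RNA, and the comparison of mouse shares at equal UMIs, were chosen only after the result was seen; those of intron number, of transcription running on and of mouse cells were set before the data were examined. Each pattern rests on 1 library per group.

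Naive genes such as DNMT3L and primed genes such as THY1 separated hTBLCs from naive hESCs, and the naive libraries also differed from every other cultured library in 2 technical respects. Their barcodes shared 12.9% to 26.9% of their 7-base starts with the other libraries, against 97.1% or more among those others, and ribosomal protein UMIs made up 38.8% or more of each naive library against at most 25.9% elsewhere. Naive hESCs at 77 h, in the same barcode pool as those at 0 h, lost the naive genes themselves, with a median of -4.29 [-4.40, -4.18]. A large naive-list difference thus arose without a change of pool. This cannot tell how much the pool added to the difference between hTBLCs and naive hESCs. The ribosomal share followed the library series and not the cell state, so it may stem from another kit version than the labels give, from handling, or from culture before E8 medium. These stay open as sources of the ribosomal share. The barcode starts argue against a single kit version for all libraries, and a kit difference would enter every ratio of a naive to another library.

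Across all genes, sriZLCs differed from hTBLCs by gene structure, which bears on which genes rose in them. A loss of mature transcripts from genes with many introns predicts lower values for such genes. Over all gene lengths the opposite was seen. Genes with at least 10 introns lay 1.504 above those with 0 or 1 on the log2 scale [1.25, 1.69]. In the middle range of gene length the difference was 0.14 [-0.36, 0.67], an interval that holds both signs, with 49 genes of 0 or 1 intron. The test cannot decide on such a loss, since gene length went with the ratios and mature and unspliced RNA were not counted apart. Uneven removal of poor cells is argued against for the maternal genes such as GDF9 and OOEP, whose list stayed at 2.66 with the stricter filter. Among genes with 5 to 9 introns, those of at least 50 kb lay 2.40 above those under 10 kb [2.20, 2.60] (0.90 and -1.50). That difference was 0.78 [0.59, 0.97] for hTBLCs over naive 0 h and 0.18 between the ends of the E8 series. Genes weak in hTBLCs, under 5 CPM, rose in general. The median was 1.97 over the 15200 without an expressed gene just upstream, against 0.12 for such genes in E8 medium at r104h over 6 h. A rise from a low level was therefore common in sriZLCs. Weak genes just downstream of an expressed gene on the same strand lay 1.12 above those on the opposite strand [0.55, 1.80] (2.79 and 1.67). Unspliced or run-on RNA may thus contribute. Both stay open, since counts of exons and introns were not used here and the run-on difference was also seen in E8 medium at r104h over 6 h (0.41 [0.024, 0.74]). It was not seen at 12 h over 6 h (-0.025 [-0.085, 0.051]).

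In the primed teratoma, 37 blood-like cells with the macrophage genes HLA-DRA (34 of 37 cells), LYZ and TYROBP and 16 cells led by surfactant genes (SFTPC at 156800 CPM) stood apart. They held 700 to 1491 UMIs per cell, against a median of 10408.5 in 5584 other cells. Free RNA from the other cells is argued against, as 12.5% of their UMIs [12.2, 12.8] (13.2% and 10.7% by cluster) fell on genes under 10 CPM in the others, against 2.77% in other cells not used to choose those genes, with the genes that led these clusters left out. The share of mouse UMIs cannot decide on mouse host cells read as human, since barcodes under 90% human UMIs were left out beforehand. The share, 1.05% [0.963, 1.14], was under 5 times the 0.495% of the other cells, the limit set beforehand against mouse cells. It also lay above that 0.495%, which was the mark set for mouse cells, so both marks were met and mouse host cells stay open. Small cells held more mouse UMIs in general, 2.62% [2.54, 2.71] in 135 other cells in the same range of UMIs. That was above the blood-like (0.73% [0.646, 0.823]) and surfactant-led (1.73% [1.54, 1.94]) cells alike. Cells or RNA of another human sample, and human lung-like tissue within the teratoma, were not tested and stay open.

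UMIs on mouse genes in the teratoma library numbered 350895, 0.51% of its total. They were not analysed for the cell types of the host.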

How the results depend on the processing

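The random lists matched on gene length and the pairing of 41 h with E8 36 h were chosen only after the result was seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group was 1 library. Among 50 list medians past 2-fold, all 50 kept their sign with every barcode, the stricter filter, TMM scaling, no mitochondrial or ribosomal protein genes, and mean per-cell CPM; 49 did after thinning, and 41 of 42 among members of at least 10 CPM. Those still past 2-fold were 50 with every barcode, 48 with the stricter filter, 45 with TMM, 49 without mitochondrial and ribosomal protein genes, 48 as a per-cell mean, 44 after thinning and 39 of 42 at 10 CPM or more. The cause was not tested for any shift.

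In hTBLCs over naive 0 h the 8-cell median of -4.82 was -4.97 with every barcode, -3.83 with the stricter filter, -5.85 with TMM, -5.11 without mitochondrial and ribosomal protein genes, -4.99 as a per-cell mean, -3.14 after thinning and -9.08 among members of at least 10 CPM. Naive genes went from -7.86 to -7.45 (stricter), -8.89 (TMM), -8.15 (no mitochondrial or ribosomal protein genes), -7.01 (thinned) and -10.09 (at least 10 CPM), and primed genes from 5.56 to 4.53 (TMM) and 5.27 (no mitochondrial or ribosomal protein genes).

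In sriZLCs over hTBLCs the 8-cell median of 1.60 was 0.67 with the stricter filter and 2.40 as a per-cell mean. The maternal median of 2.97 was 2.66, 2.65, 1.90 (thinned) and 6.49 (at least 10 CPM). Against random lists matched on gene length too, the maternal list stayed at percentile 99.0 while these moved: primed from 0.97 to 7.71, core from 5.17 to 24.4, stress response from 2.39 to 12.5, glycolysis from 6.66 to 17.2, cell cycle from 0.15 to 2.40, p53 from 1.65 to 5.18, spliceosome from 6.53 to 33.4, SR and hnRNP proteins from 55.9 to 93.2 and DNA methylation from 38.5 to 5.33.

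In the E8 series at r104h the mesendoderm median of -1.99 was -2.53 (stricter), -1.90 (TMM), -2.07 (no mitochondrial or ribosomal protein genes), -1.67 (per-cell mean), -1.73 (thinned) and -2.90 (at least 10 CPM), and glycolysis, 1.80, was 1.67, 1.88 and 1.72 under the leading 3 of these. In naive cells at 77 h the naive median of -4.29 was -4.78 with TMM and -4.44 at 10 CPM or more, and primed genes, 5.71, were 5.22 with TMM, 5.14 thinned and 6.04 at 10 CPM or more. The hypoblast median of -1.55 turned to 0.96 at 10 CPM or more and the amnion median of -1.10 to 1.18 after thinning.

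Blastoid pluripotent-like cells, 35.1%, were 37.3% at Leiden resolution 0.5 and 31.1% at 2.0; hypoblast-like cells, 28.3%, were 48.7% and 39.8%, 34.6% with 4000 variable genes and 24.6% named cell by cell. Teratoma neural progenitors, 20.4%, were 25.3% at 2.0. Mesenchyme, 22.1%, was 23.5% at 0.5, 29.02% at 2.0, 35.3% with 4000 variable genes and 25.6% cell by cell. Naive 0 h cells with at least 3 8-cell genes, 2.93%, were 1.70% at 2000 UMIs, 5.50% at 10000 and 24.5% unthinned; in sriZLCs, 0.0207%, the share was 0% at 2000 UMIs.

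Clustering each teratoma alone and comparing genes within teratoma classes were not run, as the hTBLC teratoma was not analysed here. Using every deposited barcode left the blastoid shares the same, since no cell had been removed.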

Other observations

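The hypoxia list, and the same list without genes already named, were chosen only after the result was seen. Hypoxia-response genes were higher late in the E8 series, clearly so from 56 h on. At 12 h 0 of 24 were higher and 0 lower, with a median of 0.03 [-0.036, 0.056]. NDRG1, a stress gene induced at low oxygen, went from 2.01 CPM at 6 h to 341.8 CPM at r104h, the growth factor VEGFA from 10.6 to 115.4 CPM, the mitophagy receptor BNIP3 from 127.6 to 1582 CPM, the carbonic anhydrase CA9 from 0.874 to 19.9 CPM and the peptide hormone ADM from 14.3 to 253.1 CPM. Of 24 listed genes, 16 were higher at 36 h (median 1.26 [1.21, 1.31]), 24 at 56 h (2.84) and 23 at r104h (3.97 [3.92, 4.01]). Without the 9 genes that had drawn attention to the pattern, 7, 15 and 14 of 15 were higher at these times, with medians of 0.95, 2.71 and 3.50, so at 36 h this list stayed under 2-fold. Naive hESCs at 77 h did not share it, with a median of 0.08 and 7 genes higher against 3 lower, and sriZLCs beside hTBLCs had 10 genes higher and 10 lower, with a median of -0.64, or 0.04 without the genes already named. Oxygen supply, cell density and medium age were not recorded in the labels and were not tested.

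Among the most unequal genes between hTBLCs and naive hESCs were 2 metallothioneins, which bind zinc and copper. MT1H was at 0.174 CPM in hTBLCs against 2253 CPM in naive cells, and MT1G at 0.584 against 2137 CPM, 3658-fold lower. Reads of these near-identical genes can be shared, so each value is uncertain. In blastoids MT1H and MT1G also led a pluripotent-like cluster of 249 cells, at 74.7 and 153.9 CPM.

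The imprinted transcript MEG3 separated the routes at their late pair of libraries, at 352.8 CPM in naive hESCs at 77 h and 0.116 CPM in hTBLCs at r104h. It was picked by the fixed rule as among the most unequal genes of that pair, and other imprinted genes were not examined.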
